A study of Mus musculus with 3 samples.

How the data were processed

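Single-cell RNA sequencing was done on the arcuate nucleus of the hypothalamus of male C57BL/6JRj mice, per the labels. Mice were fed standard chow (SC) for 15 days from weaning, chow for 10 days and then a high-fat high-sugar (HFHS) diet for 5 days, or the HFHS diet for 15 days. Tissue of 6 mice of a diet was pooled into 1 suspension, so the data hold 3 libraries, 1 per diet. Per the labels' protocols, the nucleus was micropunched, digested with collagenase/dispase and then papain, and prepared with a 10x Genomics droplet kit that primes at the 3' end of transcripts and adds unique molecular identifiers (UMIs). Each UMI marks 1 captured transcript molecule.

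The deposited matrices hold raw UMI counts per gene and barcode, per the file headers and the values, which were whole numbers. They were made with Cell Ranger on GRCm38, and SAMtools and Scanpy 1.4.4 were also used by the authors, per the submitters' processing notes. The matrix headers give software version 3.1.0. The gene annotation used for counting was not given in the sources used here. Each matrix listed 31253 genes, and no barcode had fewer than 500 UMIs. Of the gene identifiers, 31184 were found in the GENCODE annotation of GRCm38 used here and 69 were not. The libraries held 7116 (SC), 6204 (5-day) and 7823 (15-day) barcodes with 59315940, 52735770 and 43193012 UMIs.

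Barcodes with at least 500 detected genes and at most 20% mitochondrial UMIs were kept, which removed 668, 819 and 964 barcodes for few genes and 1459, 1222 and 1451 for mitochondrial UMIs; a barcode could meet both limits. Doublets were scored with Scrublet as built into Scanpy 1.11.5. Its automatic call marked 0% of the SC barcodes, 1.27% of the 5-day and 1.53% of the 15-day barcodes, so the automatic call did not work in the SC library. The highest-scoring barcodes were removed instead at 0.8% per 1000 barcodes, which took out 291, 211 and 344 barcodes. Counts were scaled to 10000 per cell and log-transformed, 3000 variable genes and 40 principal components were used, and cells of the 3 libraries were clustered together without integration (15 neighbours, Leiden resolution 1, seed 0). Python 3.11.15, AnnData 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, Matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.

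Clusters were called X-like from 29 sets of marker genes when at least 3 markers of a set stood among the cluster's 50 leading genes. A cluster stayed unnamed when markers of another class led its top 10 genes, when over 90% of its cells came from 1 library, or when its UMIs per cell were under its library's median divided by 3 with no own marker in the top 10. Of 33 clusters, 27 were named, giving 13 classes. The 10 classes with at least 100 cells in each library were compared. Neuron-like cells were clustered again to name subclasses, and once more without the subclass markers.

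UMIs were summed per class and library and scaled to the total UMIs of that class and library, as CPM. With 1 library per diet no test between diets was possible, and no p-value was computed. Sums have exact Poisson intervals, ratios exact conditional-binomial intervals and shares exact Clopper-Pearson intervals, all at 95%. They cover counting error only, not the spread between mice, pools or library preparations, and no difference has a replicate check. The intervals of UMI sums and UMI ratios also leave out the spread between cells, since 1 cell can hold many of a gene's UMIs. A gene was past the size rule with at least 100 UMIs in both libraries together, 30 CPM in either, a ratio of at least 1.5 and a counting interval that excluded 1.25. The named genes also had to exceed the median log2 ratio of the other classes by at least 0.5. The 8 with the largest ratio per direction were named in astrocyte-like cells and 3 in every other class. A gene past the ratio of 1.5 in the same direction in at least 7 of the 10 classes was called shared, and up to 8 per direction were named. A gene measured in fewer than 10 classes also needed 7. Up to 4 members of a gene list were named, with members that went the other way. Gene models, ribosomal protein genes and mitochondrial genes were counted but not named singly. Genes shown as members of a list need not be past the size rule.

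For 32 gene lists (682 genes, 1 of them missing from the matrices), the median log2 ratio was taken over members with at least 50 UMIs, where at least 5 were measured. Its interval came from 1000 Poisson resamples. Its percentile among 10000 random lists of the same size, matched on expression in 20 bins, describes these libraries and is not a test. A gene was marked as ambiguous in counting when it overlapped an exon of another gene on the same strand, or when over 50% of the 31-base words of its last 500 bases occurred in another gene; this held for 3544 genes.

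The size rule was tested on simulated astrocyte-like counts with 200 changed genes. For the 5-day comparison it recovered 46% of 50 genes changed 1.5-fold, 98% at 2-fold, 96% at 3-fold and 100% at 4-fold among 5784 genes, and 4 of 5587 unchanged genes passed. For the 15-day comparison it recovered 34%, 92%, 98% and 100% at the same folds among 5964 genes, and 0 of 5768 unchanged genes passed. Of 50 simulated lists with 20 genes moved 1.25-fold, 50 reached percentile 99 in either comparison. The simulated counts held counting error only, with no spread between cells or pools. The numbers of unchanged genes that passed are therefore not a rate of false calls in the real libraries.

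The groups, lists, markers, rules and most alternatives were set before the data were examined. Alternatives varied the gene minimum (250 or 1000), the mitochondrial limit (10% or none), doublet removal (none or 2 times the rate), resolution 2, clustering of each library on its own, the minimum UMIs per gene, and the scaling (totals without mitochondrial, ribosomal protein and hemoglobin genes, median-of-ratios factors, or edgeR's TMM factors as a scaling only). They also gave every cell equal weight, thinned cells to 1000 UMIs, or subtracted free RNA at 5% or 10%. Free RNA was subtracted as the profile of all UMIs of the library, from cells and unused barcodes alike, so a class's own transcripts were part of it. A further 5 alternatives were chosen after seeing the data: leaving out genes ambiguous in counting, a fixed mix of the clusters of each class that had at least 20 cells in each library (which left out AgRP-like cluster 28 of the neuron-like and cluster 24 of the oligodendrocyte-like cells), leaving out the cell with most UMIs of each gene, neuron-like cells without mixed subclusters, and neuron clustering without subclass markers. Barcodes outside the cell filter entered no comparison, except through the profile subtracted as free RNA.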

Results

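The series measured gene expression in single cells of the mouse arcuate nucleus, a hypothalamic region that controls feeding, after chow or a high-fat high-sugar diet. Each of 3 diets (SC, 5-day HFHS and 15-day HFHS) had 1 library pooled from 6 mice. After filtering, 4825 SC cells, 4041 5-day cells and 5157 15-day cells were analysed, 14023 in all, holding 49003882, 42943491 and 35083129 UMIs. Median depth was 5131, 5779 and 4130 UMIs and 2313, 2453 and 1958 genes per cell. Mitochondrial transcripts took 5.99%, 6.33% and 6.59% of UMIs and ribosomal protein transcripts 7.33%, 7.39% and 8.61%. Values below are in the order SC, 5-day, 15-day unless stated, brackets hold counting intervals, and ratios compare libraries, since no diet had a second pool.

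Astrocyte-like cells made up a larger share of the 15-day library (24.3%) than of the 5-day (19.9%) and SC (16.2%) libraries. They numbered 784, 805 and 1255, and the 15-day share was 1.5 times the SC share (log2 ratio 0.58 [0.45 to 0.71]). Ependymal-like cells, the ciliated cells that line the ventricle, took 9.74%, 9.87% and 5.06%, and the 15-day share was 0.520 of the SC share. Tanycyte-like cells, the specialised glia of the ventricle floor, took 21.2%, 18.5% and 18.7%. Microglia-like cells (12.0%, 12.7% and 12.3%) and neuron-like cells (7.61%, 7.20% and 7.74%) held similar shares in the 3 libraries. Oligodendrocyte-like cells took 9.14%, 8.44% and 8.18% and endothelial-like cells 7.92%, 8.93% and 7.41%. Oligodendrocyte precursor (OPC)-like cells took 7.07%, 6.85% and 5.47%, committed oligodendrocyte precursor (COP)-like cells 3.73%, 2.99% and 2.60%, and pericyte-like cells 2.78%, 2.70% and 2.23%. Vascular leptomeningeal-like cells were few, at 11, 18 and 60 cells (0.228%, 0.445% and 1.16%). Unnamed clusters held 1.43%, 0.891% and 3.78% of cells. Clusters 30, 31 and 32, with 25, 19 and 36 cells, came from the 15-day library only and entered no class. Among their leading genes were the peptide genes Sst, Tac2, Gal and Ghrh and the oligodendrocyte gene Opalin.

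The astrocyte order depended on how cells were grouped. With each library clustered on its own, the log2 share ratio of astrocyte-like cells at 15 days was -0.27, because a 15-day cluster of 563 cells stayed unnamed there and 562 of them were astrocyte-like in the joint clustering. There the tanycyte-like ratios were 0.41 at 5 days and 0.68 at 15 days, and the COP-like ratio was 0.16 at 15 days. With at most 10% mitochondrial UMIs the astrocyte-like ratio was 1.09 at 15 days and 0.54 at 5 days, against 0.29 [0.15 to 0.44] at 5 days in the main setting. The largest cluster of some classes differed between libraries. Cluster 1 held 51.8% of SC astrocyte-like cells, while cluster 0 held 55.9% of 5-day and 49.96% of 15-day ones. Cluster 12 held 34.9% of SC and 37.2% of 15-day tanycyte-like cells, and cluster 2 held 37.0% of 5-day ones. A Gfap-led astrocyte-like cluster, 27, took 3.95%, 10.1% and 3.43% of the class, and a Klk6-led oligodendrocyte-like cluster, 24, took 11.8%, 3.81% and 9.24% of its class. The microglia-like cluster 13, with a median of 1622 UMIs per cell, took 36.6%, 45.3% and 18.7% of its class, and the COP-like cluster 22, led by Bmp4 and Gpr17, took 37.2%, 36.4% and 47.8%. Ependymal-like cluster 8, with a median of 1808 UMIs per cell, took 79.4%, 74.9% and 61.3% of its class. Shares also depend on punching, dissociation and capture.

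**Figure D1:**
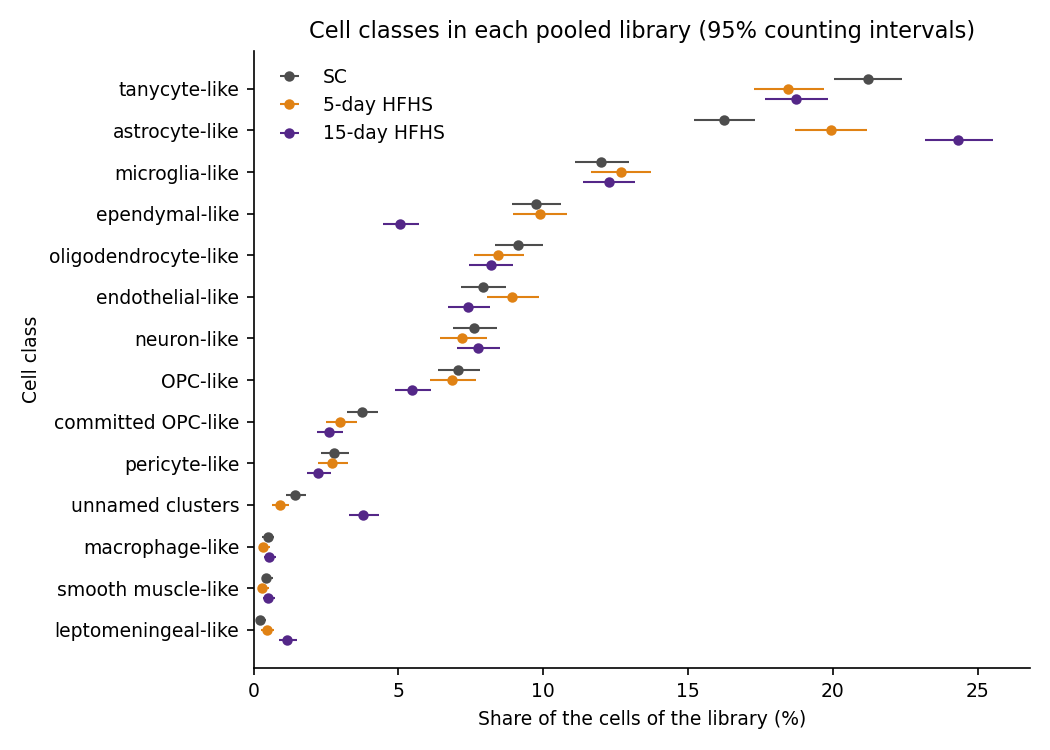
Share of the cells of each pooled library in each named cell class (horizontal axis, percent), with a point per library and 95% counting intervals as bars. Astrocyte-like cells took 16.2% of the SC, 19.9% of the 5-day and 24.3% of the 15-day library, and ependymal-like cells 9.74%, 9.87% and 5.06%.

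The comparison of the 5-day HFHS library with SC asked what a short period on the diet did to the cells of the nucleus. In astrocyte-like cells, transcripts for energy and lipid metabolism stood higher in the 5-day library. Fabp5, a fatty acid carrier, was at 164 CPM in the SC library and 288 CPM in the 5-day library (log2 ratio 0.81 [0.65 to 0.98]). Angptl4, an inhibitor of lipoprotein lipase, was at 45.6 and 76.3 CPM, and the glycolytic genes Ldhb and Gapdh were at 361 and 567 CPM and 661 and 1014 CPM. Synapse and myelin genes stood lower in the same cells.

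All 30 measured genes of nuclear-encoded oxidative phosphorylation had a ratio above 1 in astrocyte-like cells (median log2 ratio 0.36 [0.31 to 0.40], percentile 100), among them Cox8a (0.55), Ndufb8 (0.54, ambiguous in counting) and Atp5k (0.52). With a fixed mix of clusters this median was 0.16. Of 22 measured cholesterol synthesis genes 20 were higher and 2 lower (median 0.27 [0.15 to 0.32], percentile 99.99). Hmgcs1, the enzyme before the rate-limiting step, was at 131 and 173 CPM, Msmo1 at 206 and 273, Mvd at 30.8 and 42.1 and Fdps, ambiguous in counting, at 37.8 and 52.9, while Lss was at 28.9 and 25.2. None of these members was past the size rule. Glycolysis and lactate genes had 15 of 18 higher (median 0.29, percentile 99.99), 2 of them past the size rule. Aldoc had a log2 ratio of 0.54 and Pfkp one of -0.28. Fatty acid uptake and oxidation genes had 21 of 25 higher (median 0.17, percentile 99.64), and oxidative stress genes 17 of 20 higher (median 0.20, percentile 99.51). Txnip, a glucose-responsive regulator of thioredoxin, was at 62.8 and 111 CPM and past the size rule. The glucocorticoid response list had 13 of 18 higher (median 0.26, percentile 99.94). The endoplasmic reticulum (ER) stress list had a median of -0.017 and the reactive astrocyte list, with 6 of 26 genes measured, one of -0.037. Gfap, the intermediate filament of reactive astrocytes, was at 274 CPM in the SC and 373 CPM in the 5-day library.

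Interferon response genes split 6 higher and 5 lower in astrocyte-like cells, and the median of 0.28 became -0.071 without the cell with most UMIs of each gene. Ifit3, an antiviral gene, was at 11.3 and 35.0 CPM (log2 ratio 1.63 [1.04 to 2.26]) and Ifit1 at 2.34 and 17.1, but Ifitm3 was at 12.9 and 7.89. Among the other named genes, Ccn1 was at 16.0 and 31.8 CPM, the kinesin Kif5a at 39.8 and 73.6 and Tmem14a at 17.5 and 31.3. Lower in the 5-day library were the collagen Col5a3 (53.8 and 25.5 CPM), Ankrd16 (40.5 and 17.1) and the sodium pump subunit Atp1b1 (83.8 and 43.7). Transcripts of other cell types also differed. The neuropeptide Avp was at 127 and 31.3 CPM (log2 ratio -2.03), Npy at 64.3 and 28.9, and the neuronal genes Resp18 and Meg3 at 67.5 and 32.1 and 72.9 and 37.9. Oxt was higher, at 14.0 and 59.96 CPM. Of 20 measured synapse genes 20 were lower (median -0.27, percentile 0.160), and of 14 myelin genes 11 were lower (median -0.37, percentile 0.0300). The oligodendrocyte genes Apod, Trf and Cldn11 were at 35.5 and 14.2 CPM, 56.9 and 34.5 CPM and 25.7 and 14.7 CPM. The red blood cell genes Hba-a1, Hbb-bs and Hba-a2, ambiguous in counting, had log2 ratios of 3.41, 3.38 and 3.09, and 89.9%, 91.4% and 91.2% of their 5-day UMIs came from 1 cell. With at least 1000 genes per barcode Hbb-bs and Hba-a2 were at -0.16 and -0.72.

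In all, 40 genes were past the size rule as higher and 53 as lower in 5-day astrocyte-like cells, of 5948 considered. Median-of-ratios scaling gave 104 higher and 23 lower, TMM scaling 110 and 23, subtraction of 10% free RNA 106 and 80, cells thinned to 1000 UMIs 12 and 12, and a fixed mix of clusters 12 and 19.

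**Figure D2:**
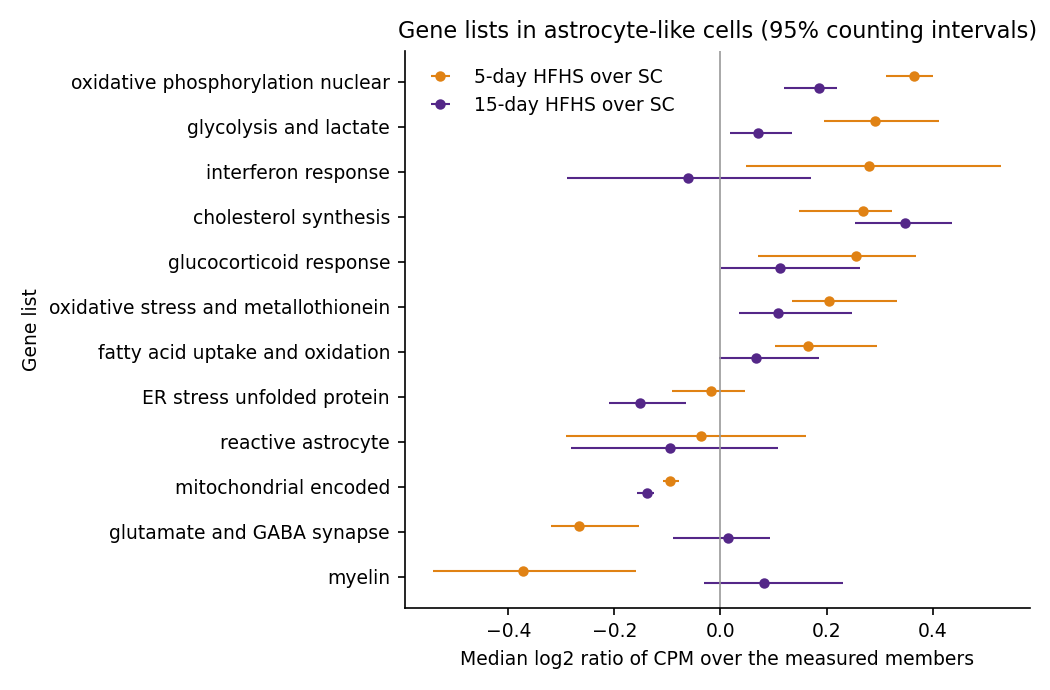
Median log2 ratio of CPM (horizontal axis) of gene lists in astrocyte-like cells for the 5-day and the 15-day HFHS library over SC, with 95% counting intervals as bars. Oxidative phosphorylation (0.36 and 0.19) and cholesterol synthesis (0.27 and 0.35) lay above 0 in both, and ER stress lay at -0.017 and -0.15.

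Microglia-like cells of the 5-day library had lower levels of genes linked to lipid-handling, disease-associated microglia. Of 20 measured genes of that list 18 were lower (median -0.15 [-0.18 to -0.061], percentile 0). Lpl, lipoprotein lipase, was at 75.0 and 44.5 CPM, Spp1, osteopontin, at 31.5 and 6.36 and Cst7 at 23.3 and 18.8. The metalloelastase Mmp12 was at 39.1 and 1.59 CPM, with 83.2% of its SC UMIs from 1 cell. Interferon response genes had 14 of 19 higher (median 0.19 [0.030 to 0.37], percentile 99.94), with Ifi27l2a at 149.7 and 243 CPM and Ifit3 at 9.58 and 30.2. This median was -0.10 in cells thinned to 1000 UMIs and -0.0048 with every cell given equal weight. The astrocyte genes Plpp3 (13.4 and 32.4 CPM) and Agt (16.4 and 38.8) stood higher, and Hbb-bt (164 and 29.3) lower with 98.2% of its SC UMIs from 1 cell and a log2 ratio of 0.64 with at least 250 genes per barcode.

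In oligodendrocyte-like cells, the protease gene Klk6 (321 and 132 CPM), the annexin Anxa5 (153 and 71.0) and the cell cycle inhibitor Cdkn1c (50.7 and 25.7) stood lower in the 5-day library. Sgk1, a kinase induced by glucocorticoids, was at 411 and 709 CPM (log2 ratio 0.79 [0.72 to 0.85]). The fixed mix of clusters left out cluster 24, which had 13 5-day cells, and the Anxa5 log2 ratio was then 0.17. The ER stress list was lower (median -0.16). Hemoglobin dominated the other side. In oligodendrocyte-like cells Hba-a2, Hba-a1 and Hbb-bs were at 1.52 and 394, 1.93 and 469 and 5.92 and 1359 CPM, with 58.6% of the 5-day Hbb-bs UMIs from 1 cell. In OPC-like cells the same genes were at 2.26 and 705, 4.97 and 805 and 10.8 and 1633 CPM, with 98.5% of Hbb-bs from 1 cell. OPC-like cells also had lower Avp (70.9 and 15.1 CPM), Frrs1 (37.9 and 19.7) and Npy (47.9 and 25.7). Avp and Npy are neuropeptides found here as free RNA, with Avp at 43.4 and 15.9 CPM over glia and vessel classes, and Npy was not past the size rule without the cell with most UMIs. COP-like cells had 19 of 22 cholesterol synthesis genes higher (median 0.29 [0.15 to 0.35]), with Mvd at 75.2 and 116 CPM and Sqle at a log2 ratio of -0.21. In thinned cells that median was -0.0096 and the Mvd log2 ratio -0.20, and with every cell given equal weight Mvd was at -0.26. Upf2 (41.5 and 16.5 CPM), Trp53inp1 (36.6 and 15.4) and Rgs16 (68.5 and 32.9) stood lower in COP-like cells. Oxt, Vtn and C1qb, genes of other cell types, were at 8.72 and 324, 2.08 and 53.1 and 9.14 and 63.2 CPM there, with 97.4%, 98.0% and 88.2% of the 5-day UMIs from 1 cell. Without that cell the Vtn log2 ratio was -0.65.

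Endothelial-like cells of the 5-day library had less Adm, a vasodilator peptide (40.7 and 22.5 CPM), less Ankrd37 (91.6 and 45.8) and less of the apelin receptor Aplnr (44.9 and 25.2). The acute-phase gene Lcn2 was at 35.0 and 77.3 CPM, and its log2 ratio of 1.14 became -0.39 without the cell with most UMIs. The astrocyte genes Agt and Slc6a11 were at 10.1 and 50.5 and 8.47 and 38.8 CPM, and the smooth muscle gene Tagln was at 17.4 and 70.8 CPM, with 88.2% of its SC UMIs from 1 cell and a log2 ratio of -0.21 at resolution 2. Ependymal-like cells had more Mal (49.4 and 93.0 CPM), Ptgds (40.2 and 74.0) and the heat shock factor Hsf1 (17.6 and 30.5), and less Avp (62.2 and 15.8), Stmn3 (41.7 and 22.3) and Snhg11 (81.8 and 48.2). Mal and Ptgds are oligodendrocyte genes and Snhg11 and Avp neuronal ones, and the Ptgds log2 ratio of 0.88 was 0.45 without the cell with most UMIs. The log2 ratio of Hsf1 was -0.40 with every cell given equal weight, and that of Snhg11 was 0.030 at resolution 2. Tanycyte-like cells had lower myelin genes, with 15 of 16 below 1 (median -0.91 [-1.04 to -0.70]), 0.094 in thinned cells. Mal was at 43.9 and 13.1 CPM and Ptgds at 156 and 86.3, while Hbb-bs was at 7.61 and 77.7 and Acta2 at 18.8 and 46.5. The Acta2 log2 ratio was -0.026 with every cell given equal weight. In pericyte-like cells Trim35 was at 75.4 and 146 CPM, Nts at 175 and 94.7 and Ndufb5 at 265 and 157.

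The comparison of the 15-day HFHS library with SC, both after 15 days on their diet, was the longer exposure. Cholesterol synthesis stood higher in 15-day astrocyte-like cells and lower in oligodendrocyte-like cells, and ER stress genes stood lower in 9 of 10 classes. In astrocyte-like cells 20 of 22 cholesterol synthesis genes were higher (median 0.35 [0.25 to 0.44], percentile 100). Mvd was at 30.8 CPM in the SC library and 46.4 CPM in the 15-day library (log2 ratio 0.59 [0.20 to 0.99]), Dhcr7 at 63.6 and 93.3, Cyp51 at 98.6 and 144 and Msmo1 at 206 and 296, while the cholesterol carrier Stard4 was at 14.4 and 13.6. Oxidative phosphorylation had 28 of 30 higher (median 0.19 [0.12 to 0.22], percentile 100), with Atp5k at 205 and 316 CPM and Atp5e at 248 and 363.

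The mitochondrially encoded list was lower in the same cells (median -0.14 [-0.16 to -0.12]), and the median mitochondrial percent of single cells of the class was 11.4% in the SC and 9.87% in the 15-day library. ER stress genes had 15 of 20 lower (median -0.15 [-0.21 to -0.066], percentile 0.0900), among them the chaperones Hyou1 (44.1 and 32.8 CPM) and Sdf2l1 (17.5 and 12.3), with Herpud1 at 94.4 and 104. The reactive astrocyte list had a median of -0.094 [-0.28 to 0.11] over 8 measured genes, and Gfap was at 274 CPM in the SC and 186 CPM in the 15-day library. Named genes higher at 15 days included the clock output gene Dbp (65.5 and 105 CPM), the immediate-early gene Jun (30.02 and 49.3), the chromatin remodelling subunit Smarcd1 (26.1 and 46.1), prohibitin Phb (29.2 and 53.5), Tubb4a (22.2 and 40.1) and Rab8b (34.3 and 61.6). Ly6e was at 20.3 and 42.2 CPM, with 42.2% of its 15-day UMIs from 1 cell, and the histone gene H1f4, ambiguous in counting, at 17.2 and 31.7. Lower were Col5a3 (53.8 and 32.0 CPM), the fatty acid receptor Ppard (33.1 and 19.1), Cfap44 (30.8 and 17.3) and Atp13a5 (39.4 and 22.5). Of the neuropeptides, Avp was at 127 and 47.4 CPM, Sst at 35.1 and 61.3 and Cartpt at 27.7 and 48.2 in these cells. The size rule gave 39 higher and 15 lower genes of 5998, against 70 and 51 with each library clustered on its own and 21 and 5 in thinned cells.

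In COP-like cells, 16 of 18 myelin genes stood lower at 15 days (median -0.49 [-0.52 to -0.44]), 7 of them past the size rule. With a fixed mix of clusters this median was -0.44. Mog was at 556 and 216 CPM and Opalin at 359 and 164, while Fa2h had a log2 ratio of 0.10. Cholesterol synthesis genes split 9 higher and 13 lower (median -0.24), and 10 and 12 in OPC-like cells (median -0.030 [-0.30 to 0.027]). In COP-like cells Hmgcs1 was at 926 and 378 CPM and Hsd17b7 at 48.6 and 89.9. The nucleotide synthesis gene Ctps was at 230.1 and 68.6 CPM, Plekhh1 at 62.3 and 16.2 and Arap2 at 194 and 65.3. Plekhh1 had a log2 ratio of 0.13 in thinned cells. Tulp3 was at 27.4 and 71.1 CPM, and Hist1h2ap and Septin5, ambiguous in counting, at 1.246 and 64.7 and 20.8 and 51.7. The ER stress list had a median of -0.24 in these cells. OPC-like cells had more of the mitosis genes Cenpe (17.6 and 55.5 CPM), Aspm (21.7 and 58.9) and Cenpa (34.3 and 74.7), whose log2 ratios turned to -1.52 for Aspm and -1.57 for Cenpa with at least 1000 genes per barcode; Cenpa was at -0.48 in thinned cells. Their ER stress list was lower (median -0.42 [-0.53 to -0.34]), with the co-chaperones Dnajb9 at 103 and 48.6 CPM and Dnajb11 at 223 and 131, Pdia3 at 721 and 441 and Hyou1 at a log2 ratio of 0.46. Ngly1 (61.0 and 24.7 CPM) and the oxysterol hydroxylase Cyp7b1 (48.8 and 21.9) stood lower. In oligodendrocyte-like cells 15 of 22 cholesterol synthesis genes were lower (median -0.20 [-0.27 to -0.10]), as were ER stress genes (median -0.31), with Pdia3 at 366 and 232 CPM. Hspa1b (63.4 and 33.8 CPM), Gsr, glutathione reductase (33.7 and 18.7), and Tmem38b (31.4 and 15.7) were lower. Hbb-bs (5.92 and 216 CPM) and Hba-a1 (1.93 and 57.9) were higher, with 97.6% and 97.5% from 1 cell and log2 ratios of -0.11 and -0.17 without it, and H2ac18, ambiguous in counting, was at 1.65 and 83.5.

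Microglia-like cells of the 15-day library had lower glycolysis genes (13 of 18, median -0.23 [-0.35 to -0.14]), with the phosphofructokinase Pfkl at 62.7 and 33.1 CPM and the lactate exporter Slc16a3 at 41.9 and 23.6. With a fixed mix of clusters this median was -0.20. ER stress genes were lower too (18 of 20, median -0.27), with Pdia3 at 652 and 435 CPM and Syvn1 at a log2 ratio of 0.039. The lipoprotein gene Apoc1 was at 22.7 and 65.6 CPM, with 43.6% of the 15-day UMIs from 1 cell, and Trmt10a at 11.8 and 30.6. Mmp12 was at 39.1 and 0.278 CPM, and Hbb-bs and Hba-a2 at 812 and 6.39 and 211 and 1.67, with 97.0% of the SC Hbb-bs UMIs from 1 cell. Hist1h2ap, ambiguous in counting, was at 1.37 and 45.0.

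In 15-day endothelial-like cells, interferon response genes were lower (19 of 23, median -0.25 [-0.35 to -0.17], percentile 0.0100). Ifit1 was at 209 and 122 CPM and Usp18 at 68.0 and 41.1, while Oas1a had a log2 ratio of 0.65; Usp18 had one of 0.34 in thinned cells. All 17 measured tight junction and blood-brain barrier genes had ratios below 1 (median -0.22 [-0.29 to -0.17]), with occludin Ocln at 321 and 223 CPM and claudin Cldn5 at 6238 and 4941. Lower levels were not limited to this list. Of the endothelial markers, Ly6c1, Pltp, Spock2, Cxcl12 and Pglyrp1 were higher and the others lower, among them Itm2a (5052 and 4082 CPM) and Bsg (21983 and 18916). Median depth of the class was 8180 UMIs per cell in the SC and 4207 in the 15-day library. The ER stress list had a median of -0.25. Lcn2 was at 35.0 and 9.97 CPM, with a log2 ratio of -1.81 that was 0.67 in thinned cells. Genes of other cell types were among those named: the fibroblast gene Dcn at 5.49 and 81.8 CPM (81.7% from 1 cell), the neuronal genes Meg3 and Snhg11 at 30.7 and 121 and 23.1 and 88.0, and Hba-a2 and Hba-a1 at 36.2 and 5.81 and 42.1 and 16.6. With each library clustered on its own the log2 ratios of Hba-a2 and Hba-a1 were 0.45 and 0.97, and with doublets removed at 2 times the rate 0.29 and 0.88. In pericyte-like cells the ER chaperones Hspa5 and Pdia3 were at 745 and 490.2 and 537 and 286 CPM (list median -0.39). The contractile gene Tagln was at 209.8 and 54.5 CPM, but its log2 ratio was 0.90 with no limit on mitochondrial UMIs. Fez2 and Nsd3 were at 178 and 81.7 and 153 and 71.5, and Ptgds and the metallothionein Mt3 at 75.4 and 238 and 212 and 531.

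Tanycyte-like cells of the 15-day library had lower immediate-early and dissociation genes (20 of 23, median -0.43 [-0.52 to -0.32]), 5 past the size rule. Junb was at 123 and 68.0 CPM, the heat shock genes Hspa1b and Hspa1a at 40.8 and 21.3 and 52.7 and 28.0, and Klf6 at a log2 ratio of 0.13. The ER stress list had a median of -0.24, with the master chaperone Hspa5 at 752 and 545 CPM, Pdia3 at 350.0 and 241 and Atf4 at a log2 ratio of 0.11. Tm4sf1 was at 166 and 86.6 CPM, and H2ac18 and Fam173a, ambiguous in counting, at 3.49 and 131 and 10.1 and 39.5. Ins2, an insulin gene, was at 3.49 and 55.6 CPM with 83.1% of the 15-day UMIs from 1 cell and a log2 ratio of -2.45 with free RNA subtracted at 5%. The profile subtracted included unused barcodes, which held 98.8% of the 15-day Ins2 UMIs. Ins2 and Ins1 were among the leading genes of tanycyte-like cluster 2. Ependymal-like cells had lower ER stress genes (19 of 20, median -0.33), glycolysis genes (14 of 18, median -0.24 [-0.32 to -0.18]) and antigen presentation genes (8 of 8, median -0.46 [-0.72 to -0.33]). Aldoc was at 557 and 309.8 CPM and Hk1 at a log2 ratio of 0.29. The glycolysis median was 0.034 with each library clustered on its own. The mix of clusters in this class also differed, with cluster 8 at 79.4% of SC and 61.3% of 15-day ependymal-like cells. Steap3 (41.1 and 14.5 CPM), Snap23 (30.1 and 11.9) and Avp (62.2 and 18.6) were lower and Sertad2 (18.2 and 37.2) higher. With each library clustered on its own the log2 ratios of Avp and Sertad2 were 0.89 and -0.23. H2ac18 and Dnaaf4, ambiguous in counting, were at 5.36 and 317 and 46.4 and 97.8.

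**Figure D3:**
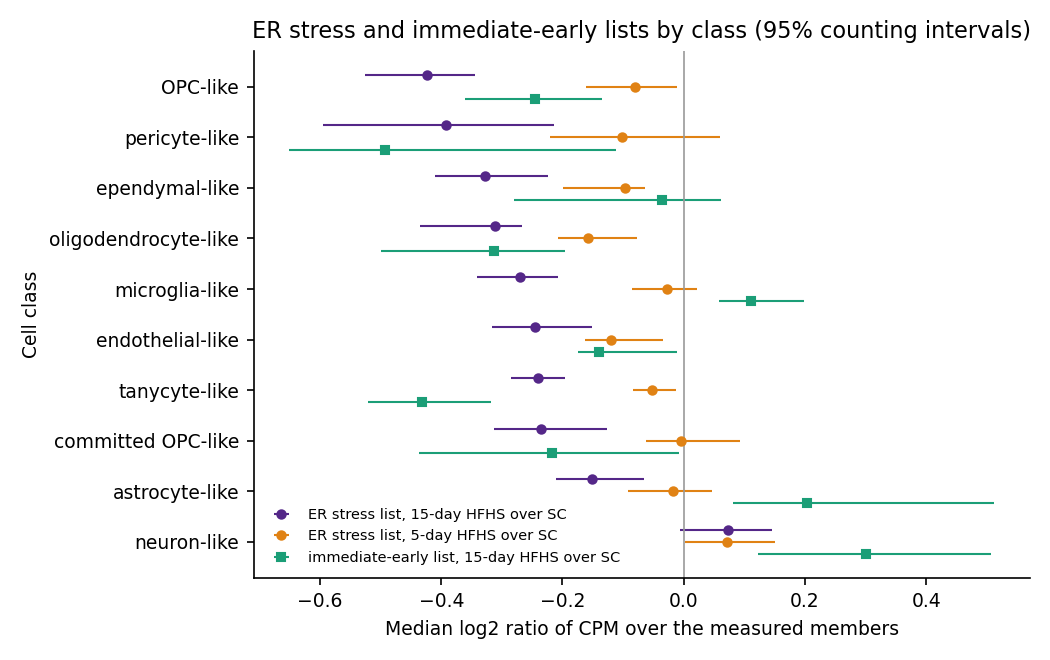
Median log2 ratio of CPM (horizontal axis) by cell class for the ER stress list in the 15-day and the 5-day library over SC (circles) and the immediate-early list in the 15-day library over SC (squares), with 95% counting intervals as bars. The 15-day ER stress median was -0.42 in OPC-like and -0.39 in pericyte-like cells, and 0.072 in neuron-like cells.

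Both comparisons used the same SC library. In astrocyte-like cells 2 genes were higher past the size rule in both (34 at 5 days and 26 at 15 days among genes considered in both) and 3 were lower in both (53 and 15). Independent lists of those sizes would share 0.152 and 0.136 genes. Simulated unchanged libraries shared 0.08 on average over both directions together, and 2 at most in 100 simulations. The simulations held counting error only and no spread between cells or pools. In microglia-like cells 3 were higher (5 and 26) and 11 lower (13 and 46) in both, against 0.0276 and 0.127 for independent lists and 0.02 simulated. In neuron-like cells 127 were higher (185 and 365) and 140 lower (246 and 673), against 9.98 and 24.5, with 0 simulated. In tanycyte-like cells none was shared among the higher (0 and 26) or the lower genes (4 and 35). The simulated libraries had only 2.13 genes past the size rule on average in astrocyte-like, 1.17 in microglia-like and 0.87 in neuron-like cells, over both comparisons. With lists that short, they cannot show how much overlap a shared library gives at the real list sizes. The SC library cannot be split, so part of the excess may come from that shared library.

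The comparison of the 15-day with the 5-day library did not use SC. ER stress genes stood lower at 15 days than at 5 days in 9 of 10 classes, with medians of -0.37 in pericyte-like, -0.34 in OPC-like, -0.26 in microglia-like, -0.25 in COP-like, -0.18 in tanycyte-like, -0.15 in oligodendrocyte-like, -0.14 in astrocyte-like, -0.13 in ependymal-like, -0.12 in endothelial-like and -0.044 in neuron-like cells. Hemoglobin and Oxt were lower across classes, with median log2 ratios of -3.56 for Hba-a2, -3.04 for Hbb-bs, -3.02 for Hba-a1 and -1.80 for Oxt. Rnaset2a (-0.80), Cdk2ap1 (-0.76) and Tomm6 (-0.62), all ambiguous in counting, were also lower. In astrocyte-like cells 63 genes were past the size rule as higher and 22 as lower, of 5925 considered. Median-of-ratios scaling gave 44 and 36, TMM scaling 42 and 42, thinning 18 and 9, and a fixed mix of clusters 52 and 7.

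Some genes differed in most classes at once. Between the 5-day and SC libraries 3 were higher, Hbb-bs in 9 of 10 classes (median log2 ratio 2.11), Hba-a1 in 7 of 10 (2.73) and Oxt in 8 of 9 (1.30), and Avp was lower in 9 of 10 (-1.34). Over all cells Hbb-bs was at 365, 985 and 156 CPM. Between the 15-day and SC libraries 33 genes were higher and 4 lower in most classes. Of the 33, 21 were ambiguous in counting, and 11 were gene models, ribosomal or mitochondrial genes. Among the first were Dynlt1b (1.00, 1.04 and 14.7 CPM over all cells), Hist1h2ap (3.73, 5.77 and 64.7), H2ac18 (2.63, 4.23 and 81.5) and Nme2 (4.82, 5.65 and 79.4), all ambiguous in counting. Gstp1, a glutathione transferase (52.6, 63.3 and 264), Ube2s (3.44, 3.44 and 14.1) and Usp50 (22.2, 27.6 and 79.1) followed and were not. Nfil3 (-0.77), Rnaset2a (-0.77) and H4c4 (-0.74) were lower. Against the 5-day library 40 were higher at 15 days, 24 of them ambiguous in counting, among them Nme2 (3.97), Dynlt1b (3.83), H2ac18 (3.75), Hist1h2ap (3.63), Ube2s (2.16), Gstp1 (2.02) and the neuropeptide Gal (1.81).

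Neuron-like cells held more AgRP-like cells, the hunger-promoting neurons of the nucleus, in both HFHS libraries. Clustered without the subclass markers, these were 5 of 367 SC cells (1.36% [0.444 to 3.15]), 33 of 291 5-day cells (11.3% [7.94 to 15.6]) and 30 of 399 15-day cells (7.52% [5.13 to 10.6]). With the markers they were 5, 32 and 32 cells, and the 5-day share was 8.07 times and the 15-day share 5.89 times that of SC (log2 ratios 3.01 [1.64 to 4.73] and 2.56 [1.19 to 4.27]). Between the HFHS libraries the log2 ratio was -0.46 [-1.21 to 0.30]. Unnamed subclusters held 75.5%, 75.6% and 69.7% of neuron-like cells. No POMC-like subcluster was named in this setting, and with no mitochondrial limit 51, 19 and 67 cells were (4.26%, 2.10% and 5.51%). Mixed subclusters led by markers of endothelial cells (96 cells), oligodendrocytes (32), red blood cells (14) and OPCs (13) were part of the neuron-like class.

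Agrp, ambiguous in counting, was at 359, 992 and 845 CPM in neuron-like cells and Npy at 808, 2331 and 1945 CPM, with log2 ratios to SC of 1.47 and 1.24 for Agrp and 1.53 and 1.27 for Npy. In SC, 39.1% of Agrp UMIs came from 1 cell. The fixed mix of clusters left out the AgRP-like cluster, which had 5 SC cells, and in the other neuron-like cells the 5-day log2 ratios were -0.28 and -0.046. Pomc, the precursor of the appetite-lowering melanocortin, was at 338, 1222 and 246 CPM, with 47.6% of the 5-day UMIs from 1 cell. Its 5-day log2 ratio of 1.85 was -3.17 with at most 10% mitochondrial UMIs and -1.77 with at least 1000 genes per barcode. Its 15-day log2 ratio of -0.46 [-0.58 to -0.34] was 0.15 in thinned cells and 0.042 with no mitochondrial limit. Cartpt was at 393, 1005 and 375 CPM. Sst was at 789.8, 486 and 734 CPM, and its 15-day log2 ratio of -0.11 turned to 0.093 with median-of-ratios and 0.086 with TMM scaling and 0.18 with no mitochondrial limit, and its 5-day ratio was 0.038 with doublets removed at 2 times the rate. Tac2, a peptide gene of KNDy neurons, was at 71.7, 16.9 and 251 CPM, and its 5-day log2 ratio of -2.08 was 0.50 with no doublets removed. Kiss1 had 0 UMIs in all 3 libraries. Gal was at 181, 237 and 159 CPM, Ghrh at 74.7, 102 and 82.1, Avp at 195, 357 and 437 and Oxt at 159, 89.5 and 173. The 15-day neuron-like values of Sst, Tac2, Gal and Ghrh leave out unnamed clusters 30, 31 and 32, found only in that library. Without mixed subclusters the Oxt log2 ratio was -3.97 [-4.42 to -3.54] at 5 days instead of -0.83, and 3.72 between the HFHS libraries instead of 0.95; 75.2% of the 5-day Oxt UMIs came from 1 cell. Free RNA set the background: in glia and vessel classes Agrp was at 10.9, 8.14 and 19.5 CPM, Npy at 43.8, 42.6 and 54.3, Pomc at 41.2, 44.8 and 63.7, Sst at 13.8, 9.82 and 28.5, Avp at 43.4, 15.9 and 25.2 and Oxt at 7.39, 37.5 and 5.73. Part of the 5-day Oxt value came from 1 COP-like cell. Without the cell with most UMIs the COP-like Oxt log2 ratio was 0.35 instead of 5.22. From 5 to 15 days the log2 ratio was -2.31 for Pomc, -1.42 for Cartpt, -0.23 for Agrp and 3.89 for Tac2.

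**Figure D4:**
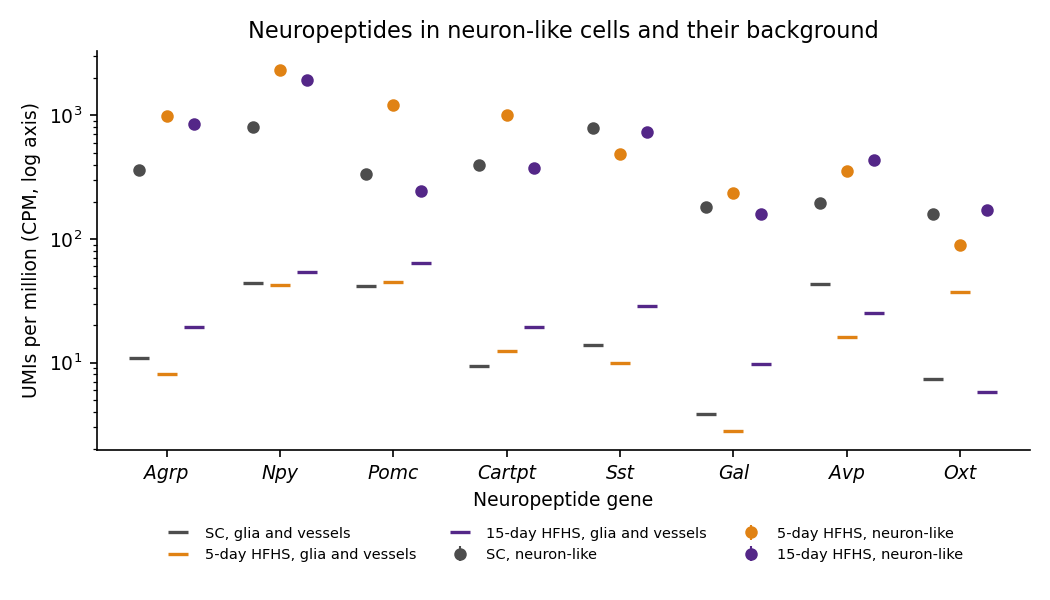
CPM (vertical log axis) of 8 neuropeptide genes in neuron-like cells of each library (circles, with 95% Poisson intervals) and in glia and vessel classes as background (dashes). Agrp was at 359 CPM in SC, 992 CPM in 5-day and 845 CPM in 15-day neuron-like cells, against 10.9, 8.14 and 19.5 CPM in the background.

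The median log2 ratio of all genes in neuron-like cells was -0.14 at both 5 and 15 days, and median-of-ratios scaling moved it by 0.17 and 0.22 and TMM scaling by 0.18 and 0.21, so lists are given relative to it. Oxidative phosphorylation was higher by 0.59 at 5 days and 0.82 at 15 days relative to that median, with Uqcrh at 343 and 579 CPM in the SC and 5-day libraries and Atp5k at 257 and 568 in the SC and 15-day libraries. With a fixed mix of clusters, without the AgRP-like cluster, the 5-day median was -0.011 instead of 0.45. The median mitochondrial percent of neuron-like cells, a sign of RNA quality, was 11.9%, 8.45% and 7.24%, and with at most 10% mitochondrial UMIs the oxidative phosphorylation medians were 0.086 at 5 days instead of 0.45 and 0.11 at 15 days instead of 0.68. Immediate-early genes were higher by 0.62 and 0.44, with Fos at 18.3 and 48.6 CPM and Junb at 26.1 and 51.2 at 5 days and Fos at 53.6 at 15 days. The 15-day median of 0.30 was -0.015 with at most 10% mitochondrial UMIs. Synapse genes lay at -0.21 and -0.16. Myelin genes, from another cell type, lay at -1.03 and -0.74, with Mag at 55.7 and 19.8 CPM at 5 days. With each library clustered on its own the 15-day myelin median was 2.09. Serpina3n, an acute-phase protease inhibitor, was at 51.1 and 201 CPM at 5 days and 116 at 15 days. Nts (5.96 and 35.4 CPM) and Crabp1 (100.8 and 24.6) at 5 days and Cck (1.83 and 31.2) and Gstp1 (21.5 and 183) at 15 days were also named, with 63.4% of the 5-day Nts, 55.4% of the 5-day Crabp1 and 75.0% of the SC Cck UMIs from 1 cell. Hcrt, the orexin gene, was at 49.3 and 2.86 CPM at 5 days and 0.547 at 15 days, with 93.0% of its SC UMIs from 1 cell. Its 5-day log2 ratio was 0.13 with no mitochondrial limit and 1.09 in thinned cells, and that of Crabp1 was 0.31 with every cell given equal weight. Nme2, ambiguous in counting, was at 3.44 and 108 CPM, and the vessel gene Vtn and Hba-a2 at 80.9 and 4.38 and 1288 and 224. With no doublets removed the 15-day log2 ratios were 0.75 for Vtn and 2.45 for Hba-a2, without mixed subclusters Vtn was at 0.25, and 86.1% of the 15-day Hba-a2 UMIs came from 1 cell.

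Neuron-like counts moved with the scaling. The size rule gave 198 higher and 246 lower genes at 5 days, 384 and 673 at 15 days and 59 and 63 between the HFHS libraries. Median-of-ratios scaling gave 539 and 77, 885 and 191, and 87 and 51, and TMM scaling 564 and 76 at 5 days and 868 and 200 at 15 days.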

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

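Several values stood on opposite sides of SC at 5 and at 15 days, and none of these differences was tested, since each diet had 1 library. Cholesterol synthesis genes in COP-like cells had a median log2 ratio of 0.29 at 5 days and -0.24 at 15 days, and -0.53 between the 15-day and 5-day libraries. In tanycyte-like cells, glycolysis and lactate genes had medians of 0.061 and -0.19 (-0.22 between the HFHS libraries) and immediate-early and dissociation genes 0.058 and -0.43 (-0.36). The neuropeptide Sst in astrocyte-like cells had log2 ratios of -0.81 and 0.81 (1.62 between the HFHS libraries), beside free Sst RNA of 13.8, 9.82 and 28.5 CPM in glia and vessel classes. In endothelial-like cells, Hba-a1 had log2 ratios of 0.66 and -1.34 (-2.0) and the acute-phase gene Lcn2 1.14 and -1.81 (-2.955). Lcn2 was at -0.39 at 5 days without the cell with most UMIs and at 0.67 at 15 days in thinned cells, and 15-day Hba-a1 was at 0.97 with each library clustered on its own and at 0.88 with doublets removed at 2 times the rate. Tac2 in neuron-like cells had log2 ratios of -2.08 and 1.81 (3.89), with 68.4% of its SC UMIs from 1 cell. Without the cell with most UMIs they were -0.83 and 3.11, and with no doublets removed the 5-day ratio was 0.50.

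Barcodes outside the cell filter of the 15-day library held transcripts of pancreatic islet hormones. Ins2 was at 9788 CPM there, against 141 CPM in the SC and 158 CPM in the 5-day library. Ins1 was at 3028 CPM against 42.5 and 51.8, Iapp at 502 against 6.30 and 7.35, and Ppy at 308 against 2.13 and 2.96. Pyy was at 145 CPM against 2.13 and 2.14, and Gcg at 30.8 CPM against 1.45 and 2.45. Over 50 Ins2 UMIs were found in 6 SC, 6 5-day and 239 15-day barcodes, with a median of 128 genes in the 15-day ones, and 98.8% of the 15-day Ins2 UMIs lay in barcodes that were not used as cells. The source of these transcripts was not tested.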

How the results depend on the processing

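No paired analysis was possible because each diet had 1 library, and for the same reason no library could be left out in turn. The alternatives that left out genes ambiguous in counting, fixed the cluster mix, left out the cell with most UMIs of each gene, left out mixed neuron subclusters or clustered neurons without subclass markers were chosen after seeing the data; the others were planned. Of 3709 log2 ratios of named genes under the alternatives, 3023 stayed within the main counting interval, 641 moved outside it and 45 reversed. For genes, lists and shares, a value was counted as reversed only where its main interval excluded equal levels in the libraries compared. Other changes of direction were counted as moved or, within the interval, as stayed. Of 1332 list medians 1080 stayed, 242 moved and 10 reversed, and of 299 class share ratios 253 stayed, 41 moved and 5 reversed. Counts past the size rule were within 1.5 times of the main count in 135 of 168 values and counts of shared genes in 57 of 78. All 27 share ratios of AgRP-like cells stayed within the main interval. Leaving out the cell with most UMIs of each gene kept 83 of 93 (5-day), 46 of 54 (15-day) and 74 of 85 (15-day over 5-day) astrocyte-like genes past the size rule. Of 133 named values, 30 had over 50% of the UMIs of a library in 1 cell. Thinning left out 335 SC, 286 5-day and 398 15-day cells with under 1000 UMIs. In the values below, the log2 ratios of a gene or list are to SC unless stated, and the cause was not tested except where given.

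With at most 10% mitochondrial UMIs, the astrocyte-like log2 share ratio was 0.54 at 5 days and 1.09 at 15 days, the 15-day neuron-like immediate-early median -0.015 and the 5-day neuron-like Pomc ratio -3.17. With no mitochondrial limit, the 5-day astrocyte-like share ratio was 0.45, its oxidative phosphorylation median 0.30, neuron-like Hcrt 0.13 at 5 days, and at 15 days pericyte-like Tagln 0.90 and neuron-like Pomc 0.042 and Sst 0.18. With at least 1000 genes per barcode, 5-day Hbb-bs and Hba-a2 in astrocyte-like cells were -0.16 and -0.72, 5-day neuron-like Pomc -1.77, and 15-day OPC-like Aspm and Cenpa -1.52 and -1.57; with at least 250 genes, 5-day microglia-like Hbb-bt was 0.64. With no doublets removed, the 5-day astrocyte-like oxidative phosphorylation median was 0.31, 5-day neuron-like Tac2 0.50, and 15-day neuron-like Vtn and Hba-a2 0.75 and 2.45. With doublets removed at 2 times the rate, 15-day endothelial-like Hba-a2 and Hba-a1 were 0.29 and 0.88 and 5-day neuron-like Sst 0.038.

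At resolution 2, the 5-day astrocyte-like share ratio was 0.45, endothelial-like Tagln -0.21 and ependymal-like Snhg11 0.030. With each library clustered on its own, 15.2%, 1.96% and 12.9% of cells were unnamed. The astrocyte-like share ratio was then -0.27 at 15 days and -0.46 over 5 days, since a 15-day cluster that was 99.8% astrocyte-like in the joint clustering had no name. An SC cluster of 478 cells, 65.3% tanycyte-like in the joint clustering, also had none, and tanycyte-like share ratios were 0.41 and 0.68. COP-like cells were at 0.16 at 15 days. In 15-day astrocyte-like cells 121 genes were past the size rule, and the cholesterol, oxidative phosphorylation and ER stress medians were 0.44, 0.35 and -0.058. Other 15-day values there were 0.034 for glycolysis and -0.92 for mitochondrially encoded genes in ependymal-like cells, 2.09 for neuron-like myelin genes, 0.45 and 0.97 for endothelial-like Hba-a2 and Hba-a1, and -0.23 and 0.89 for ependymal-like Sertad2 and Avp.

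With cells thinned to 1000 UMIs, fewer counts left 24 (5-day), 26 (15-day) and 27 (15-day over 5-day) astrocyte-like genes past the size rule and 18 genes higher in most classes at 15 days. Thinned 5-day medians were 0.29 for astrocyte-like oxidative phosphorylation, -0.0096 for COP-like cholesterol synthesis, -0.10 for microglia-like interferon response and 0.094 for tanycyte-like myelin genes. Thinned gene ratios were 1.09 for Hcrt (neuron-like, 5-day), -0.20 for Mvd (COP-like, 5-day), and at 15 days 0.13 for COP-like Plekhh1, 0.67 and 0.34 for endothelial-like Lcn2 and Usp18, -0.48 for OPC-like Cenpa and 0.15 for neuron-like Pomc. With every cell given equal weight, 5-day values were 0.31 for astrocyte-like oxidative phosphorylation, -0.0048 for microglia-like interferon response, -0.40 for ependymal-like Hsf1, 0.31 for neuron-like Crabp1, -0.026 for tanycyte-like Acta2 and -0.26 for COP-like Mvd.

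Median-of-ratios and TMM scaling put 5-day astrocyte-like cholesterol synthesis at 0.35 and 0.35, oxidative phosphorylation at 0.44 and 0.45, and 15-day neuron-like Sst at 0.093 and 0.086. Subtracting free RNA at 10% gave 186 genes in 5-day astrocyte-like cells and an oxidative phosphorylation median of 0.40, and at 5% a 15-day tanycyte-like Ins2 ratio of -2.45. Without genes ambiguous in counting, 12 genes were higher in most classes at 15 days, by construction. A fixed cluster mix gave 31 genes in 5-day astrocyte-like cells, oxidative phosphorylation medians of 0.16 in astrocyte-like and -0.011 in neuron-like cells, and 5-day ratios of 0.17 for oligodendrocyte-like Anxa5, and -0.28 and -0.046 for neuron-like Agrp and Npy, in a mix that left out the AgRP-like cluster, as it left out oligodendrocyte-like cluster 24. Without the cell with most UMIs, the 5-day astrocyte-like interferon median was -0.071, COP-like Vtn -0.65, endothelial-like Lcn2 -0.39, and 15-day oligodendrocyte-like Hbb-bs and Hba-a1 -0.11 and -0.17, since 1 cell held most of their UMIs. Without mixed subclusters, 15-day neuron-like Vtn was 0.25.

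Neuron-like counts past the size rule moved by over 1.5 times most often. Against 444 genes at 5 days, there were 150 with no mitochondrial limit, 990 with doublets removed at 2 times the rate, 983 with equal weights, 54 thinned, 66 with a fixed mix and 801 without mixed subclusters. Against 1057 at 15 days, there were 264 with at most 10% and 502 with no limit on mitochondrial UMIs, 621 with no doublets removed, 2647 with libraries clustered apart, 600 with equal weights, 97 thinned, 109 with a fixed mix and 366 without mixed subclusters. Against 122 between the HFHS libraries, there were 314, 59, 759, 679 and 21 with the 10% limit, no limit, libraries clustered apart, equal weights and thinning. Against 40 genes higher in most classes over the 5-day library, there were 13 with thinning and 16 without genes ambiguous in counting.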

Other observations

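The mitochondrially encoded list lay above percentile 99 of random lists in 6 of 10 classes at 5 days, with medians from 0.14 to 0.37, and in 7 of 10 at 15 days, with medians from 0.21 to 0.47. At 15 days these genes, which code for subunits of the respiratory chain, had medians of 0.22 in microglia-like, 0.27 in endothelial-like, 0.21 in oligodendrocyte-like, 0.35 in OPC-like, 0.31 in tanycyte-like, 0.30 in ependymal-like and 0.47 in pericyte-like cells, against -0.14 in astrocyte-like and -0.25 in neuron-like cells. The ependymal-like median was -0.92 with each library clustered on its own. The median mitochondrial percent of single cells, a sign of RNA quality, moved the same way, with 2.15% in SC and 4.55% in 15-day ependymal-like, 3.75% and 4.48% in endothelial-like, 4.21% and 5.51% in pericyte-like and 3.93% and 4.53% in OPC-like cells. It counts the same transcripts as the list, so it is no separate evidence. Some list members were also among the genes higher in most classes at 15 days, in part ambiguous in counting. Of 556 list medians against SC, 153 lay beyond percentiles 1 and 99, where uniform percentiles would put 11.1. The random lists drew their members independently, and the medians share genes and libraries. The value of 11.1 is therefore not what the absence of a diet effect would give.

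Other neuron subclasses, clustered without the subclass markers, also differed in share. VMH-like neurons, like those of the neighbouring ventromedial nucleus, were 54, 23 and 38 cells (14.7%, 7.90% and 9.52% of neuron-like cells). Dopaminergic-like neurons were 48, 16 and 40 (13.1%, 5.50% and 10.0%), and neurons like those of the suprachiasmatic nucleus, the circadian pacemaker, 1, 2 and 16 (0.272%, 0.687% and 4.01%). With the markers kept, the last shares were 1.83%, 3.83% and 3.50% with at least 1000 genes per barcode. They were 1.66%, 3.54% and 5.65% with doublets removed at 2 times the rate. The VMH-like share was highest in SC in every setting, but which HFHS share was lower varied. VMH-like shares were 13.04%, 12.6% and 7.07% with at most 10% mitochondrial UMIs, and 12.8%, 11.2% and 8.55% with no limit. They were 12.01%, 6.14% and 5.71% with each library clustered on its own. In all other settings the 5-day VMH-like share was the lowest. The order of the dopaminergic-like shares depended on the clustering, with 8.45%, 5.84% and 10.0% with the markers kept, 4.35%, 12.6% and 16.8% with at most 10% mitochondrial UMIs and 5.31%, 2.17% and 1.48% with each library clustered on its own.

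The tests of explanations in the next 3 paragraphs were chosen after the result was seen, and the diet itself stayed an open, untested explanation in each.

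At 15 days 33 genes were higher in most classes at once, with a median log2 ratio of 1.36 against 0.14 for the same genes at 5 days. Lower depth per cell stays open as an explanation. After thinning, 28 of the 33 kept a median ratio of at least 1.5, although only 18 genes were then past that ratio in most classes. Random thinning leaves the expected proportions of each cell unchanged, so it cannot decide on depth. Of the 33 genes, 63.6% overlapped another gene or shared most of their last bases with one, against 4.75% of 10085 genes measured in as many classes. A candidate explanation is a difference in how reads of such genes were counted in the 15-day library, while the 12 genes not ambiguous in counting stay unexplained.

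ER stress genes were lower in 9 of 10 classes at 15 days. Lower depth per cell stays open here too, since random thinning leaves the expected proportions of each cell unchanged and cannot decide on it. The median over 9 classes was -0.32 with thinned cells and -0.25 without, and pericyte-like cells had no thinned value. Thinning took the median from -0.27 to -0.094 in microglia-like cells and from -0.15 to -0.098 in astrocyte-like cells. An SC library that stands apart from both others is argued against as the whole explanation, since 9 of 10 classes were also lower than at 5 days, but it may hold a part, since the list was below SC at 5 days in 5 of 10 classes (-0.16 in oligodendrocyte-like and -0.12 in endothelial-like cells). A weaker dissociation response in the 15-day suspension may account for 6 of the other 7 classes (COP-, endothelial-, oligodendrocyte-, OPC-, pericyte- and tanycyte-like), where immediate-early genes were lower too. In astrocyte-like and microglia-like cells the immediate-early median was higher (lowest bound 0.058), so the lower ER stress list did not go with lower immediate-early genes there. These classes were grouped by that same value, so it is no separate test of the explanation. No gene was on both lists.

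AgRP-like cells took a larger share of neuron-like cells in both HFHS libraries. If this reflected more AgRP neurons in the tissue, each with the same Agrp RNA, free Agrp RNA would be expected to be higher. The least rise expected was set at the lower bounds of the share ratios, 1.64 (5-day) and 1.19 (15-day) on the log2 scale. Free Agrp RNA was at -0.42 and 0.84, beside a median of -0.19 and 1.04 for 5 other neuropeptides. Relative to them it was at -0.23 and -0.21. Agrp in neuron-like cells, at 1.47 and 1.24, was itself below the bound at 5 days, so equal Agrp RNA per neuron may not hold. A recovery of AgRP-like cells that differed between the suspensions may account for the shares, but this test cannot decide it. More arcuate tissue in the punches would also raise free Agrp RNA, which was lower than in SC at 5 days (-0.42) but higher at 15 days (0.84). The other peptides were higher at 15 days too (median 1.04), so more arcuate tissue stays open there. Values relative to those peptides would not show it if they came from the same tissue. The dopaminergic-like neurons do not settle it, because they stayed below the AgRP-like bound in 6 of 9 clusterings at 5 days and in 6 of 9 at 15 days, but reached it in the others.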
